A study of Rattus norvegicus with 2 samples.

How the data were processed

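Primary hepatic stellate cells were isolated from male Sprague-Dawley rats of 400 to 600 g and cultured in medium with 20% fetal bovine serum, per the labels' protocols. RNA was extracted with a miRNA kit and sequenced on an Ion Proton instrument, per the labels' protocols. The groups were pressure, with 1 sample, and control, with 1 sample. The protocol text on pressure is the same for both samples, so the groups were taken from the treatment label.

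The series has 1 table. Its values are whole numbers, deposited by the authors as read counts per mature miRNA or predicted miRNA arm. FastQC is named in the submitters' processing notes. The aligner, counter, miRNA database version, genome build, use of strand and treatment of reads that match several entries are not given in the sources used here. The table has 2 columns of counts, named by sequencing barcode alone. No label or header used here links a barcode to a sample, and linking them by column order or by the values would have been a guess, so both columns were left out of every computation. They were viewed to find their unit, and the most abundant entries of each were seen in doing so. The entries miR-126a-3p and miR-223-3p, known from endothelial and myeloid cells, were seen to be high in both columns, as was miR-21-5p, known from activated stellate cells and many other cells. This left open whether the columns are libraries of stellate cells. No value is given for this, and it was not tested. No total, ratio, share or interval was computed from them. The comparison planned before the data were examined, a scaled ratio per miRNA with a counting interval and a rank of each miRNA list among random lists, was not run. Also planned and not run were the correlation of the 2 libraries, the share of reads of the most abundant miRNAs and the arm ratio of each precursor. The correlation does not depend on which column is which sample, but was left out with the other count results. The rule for naming miRNAs rested on those ratios and on mean abundance over both columns, so it was not applied. The part on mean abundance does not need the barcodes tied to samples, but was left out with the counts. The miRNAs named here were therefore chosen after the table, its counts included, had been viewed.

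The text columns of the table, which belong to no sample, were analysed with Python 3.11.15 and pandas 2.3.3, and plotted with matplotlib 3.10.9. In the copy of the table used here 5 lines were blank, what they held was not analysed here, and all counts and percentages of entries are over the other lines. Entries were sorted by the prefix of their name into rat, mouse, human and predicted. The 24 miRNA lists were matched by exact rat name, so a miRNA listed only under a mouse name or as a predicted arm was not counted as found. Pairs of rat entries were called when they shared a stretch of at least 16 consecutive bases, on the same strand or as reverse complements. The pair search was tested on simulated data of 600 sequences. It recovered 100 of 100 planted same-strand pairs and 100 of 100 planted complementary pairs, with 0 false pairs of either kind. Each planted pair shared an exact stretch of at least 18 bases, so recovery of pairs with a mismatch inside the stretch was not tested. Where an entry listed several precursors, each was counted as a name of its own. Precursor names were looked up among the synonyms of 466 miRNA genes in a RefSeq table of GRCr8, where 442 of 446 matched. That table was used only for the order of genes, since the build behind the deposited table is not known. Shared stretches of at least 14, 18 and 20 bases were tried as alternatives.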

Results

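Per the labels, small RNA was sequenced from primary hepatic stellate cells of male Sprague-Dawley rats. Hepatic stellate cells are the pericytes of the liver sinusoid, and in culture they turn into collagen-producing myofibroblasts. The design held 1 sample of cells loaded with 10 mmHg of gas pressure for 1 h after 14 days of culture, and 1 control sample. The design asks how the miRNA profile of stellate cells differs between pressure and control. In the treatment labels, the word activated stands with the pressure sample only. The table of the series names its 2 columns of read counts only by sequencing barcode, and the labels used here tie neither barcode to a sample. It was also left open, and not tested, whether those columns are libraries of stellate cells. Because the barcodes could not be tied to samples, the read counts were not used. No miRNA is reported here as higher or lower under pressure. No depth per sample is given for the same reason. With 1 sample per group the design has no replicate check in any case.

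Described here is the set of miRNA entries that the table lists, by name and sequence. The lines analysed held 12498 named entries. Of these, 723 carried rat miRNA names from 446 distinct precursor names, 368 carried mouse names and 749 carried human names. The other 10658 entries, 85.3% of those analysed, were predicted arms named by a chromosome and a running number, with 5330 called mature and 5328 called star. A mouse or human miRNA name was attached to 2448 of the predicted arms, 1319 of them mouse and 1129 human. These numbers describe what was listed and say nothing on how strongly any entry was expressed.

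The listed rat entries were compared with miRNAs known from stellate cell biology and from other cell types of the liver. Of 189 miRNAs in 24 lists drawn up before the data were examined, 183 were found by their rat name. The table listed 446 rat precursor names, of which 442 matched names among 466 RefSeq miRNA genes. With so full a catalogue, nearly any list of rat names would be found almost in full, so the coverage below describes the catalogue. All 3 members of the miR-29 family, known as repressors of collagen genes, were found, as were all 5 members of the miR-30 family. The list of miRNAs reported as raised in stellate cell activation or fibrosis had 18 of 19 members found, among them miR-21-5p and miR-214-3p. The list reported as lowered had 21 of 22 found, among them miR-150-5p and miR-9a-5p. The list reported as responding to mechanical load in other cells had 19 of 20 found. All 55 members of the list for the imprinted Dlk1-Dio3 cluster were found. For other cell types, the hepatocyte list, which holds miR-122-5p, was found in full with 5 of 5, the endothelial list with 3 of 3, the leukocyte list with 6 of 7, the erythroid list with 4 of 5 and the epithelial and cholangiocyte list with 5 of 5. The striated muscle list was found in full as well, with 7 of 7. No read count was used here, so being listed by name does not show that a miRNA, or the cell type it marks, was present in the cells.

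Rat entries formed families with a shared seed, bases 2 to 8 counted from the 5′ end, the part of a miRNA that pairs with its targets. The 723 rat entries held 605 distinct seeds, and 194 entries, or 26.8%, shared theirs with at least 1 other rat entry. The let-7 seed was the most common, with 8 entries: let-7a-5p, let-7b-5p, let-7c-5p, let-7d-5p, let-7e-5p, let-7f-5p, let-7i-5p and miR-98-5p. The miR-30 seed had 6 entries, the 5 miR-30 members and miR-384-5p. The seed of miR-34a-5p, a miRNA induced by p53, had 5 entries, which included miR-449a-5p and miR-449c-5p.

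Some rat miRNAs were listed beside an identical, near-identical or complementary entry, which bears on how reads can be divided between them. On the same strand, 27 pairs of rat entries shared a stretch of at least 16 consecutive bases. This number moved with the minimum, from 44 pairs at 14 bases to 4 at 20. The rule misses near-identical entries whose mismatch lies near the middle. The miR-29a-3p and miR-29c-3p entries, which differ only at a base near the middle, were not among the 27. The let-7a-1-3p and let-7c-2-3p entries were identical over all 22 nt. The miR-23a-3p and miR-23b-3p sequences, each of 21 nt, shared 18 consecutive bases, and so did miR-27a-3p and miR-27b-3p. Another 59 pairs were complementary over at least 16 bases, and 36 of these over at least 20. The sequence tgaggtagtaggttgtatagtt of let-7a-5p was complementary over all 22 nt to miR-3596a, listed as aactatacaacctactacctca. Further full-length complements of 22 nt included miR-125b-5p with miR-3588 and miR-210-3p, the hypoxia-induced miRNA, with miR-3574. The hepatocyte miRNA miR-122-5p was complementary over 20 bases to miR-3591, and the endothelial miRNA miR-126a-5p over 17 bases to miR-126b. In 48 of the 59 complementary pairs, precursor genes stood next to each other in the order of miRNA genes of the rat assembly GRCr8. Where an entry had several precursors, it was enough that any of them was adjacent. Of the other complementary pairs, 3 were arms of the same precursor, 7 were not adjacent and 1 had a precursor without a match. Among the 27 same-strand pairs, 6 were adjacent. Distance and strand of the genes were not compared.

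In all, 137 of the 723 rat entries, or 18.9%, belonged to at least 1 pair of either kind at a minimum of 16 bases, and 77 at 20. At 16 bases, 41 of the 183 members found over all lists had such a partner, and the share differed between families. All 3 miR-29 members and 6 of the 8 let-7 members found had such a partner, as did 6 of 11 in the miR-23/24/27 clusters. No member had one among the 11 of the miR-17 cluster and its paralogs. The same held for the 4 arms of miR-143 and miR-145 and the 4 arms of miR-221 and miR-222. This does not show that they lack near-identical entries, since a mismatch near the middle breaks the shared stretch. In the miR-17 list, miR-17-5p, miR-20a-5p, miR-20b-5p, miR-93-5p and miR-106b-5p shared the same seed. Of the list reported as lowered in stellate cell activation, 10 of 21 members had a partner, and of the list reported as raised, 4 of 18. These lists overlap the families above. The lowered list holds all 3 miR-29 members and let-7a-5p, and the raised list holds miR-27a-3p and miR-27b-3p. By kind, 7 members of the lowered list had a same-strand partner and 8 a complementary one. In the raised list 2 had a same-strand partner and 2 a complementary one. At a minimum of 20 bases, 6 lowered and 1 raised members had a partner of either kind. At that minimum a partner was left for 4 let-7 members, 2 miR-29 members and 1 member of the miR-23/24/27 clusters. For pairs in which an entry is complementary to its partner over its full length, counting that ignores strand cannot tell all of the reads apart, while counting by strand can, and which was used is not given in the sources used here. These are counts over named sequences with no sampling error, so no test was made.

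Predicted arms were shorter than named miRNAs. Their median length was 17 nt, against 22 nt for the rat, mouse and human entries. Sequences of 17 nt or shorter made up 54.6% of the predicted arms and 1.11% of the rat entries. Across the entries analysed, 1230 sequences stood on more than 1 entry and covered 2803 entries. The most repeated sequence, gggctggagagatggct, stood on 14 entries. Among the rat entries, 54 had another entry of identical sequence. A mouse-named entry was identical to 24 rat entries and a human-named entry to 32. Of the 9853 predicted arms of at least 16 nt, 46, or 0.467%, shared at least 16 bases with a rat entry on the same strand. At a minimum of 14 bases 83 predicted arms did, and at 18 bases 8. The 54.6% of predicted arms that are 17 nt or shorter cannot share 18 bases.

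**Figure D1:**
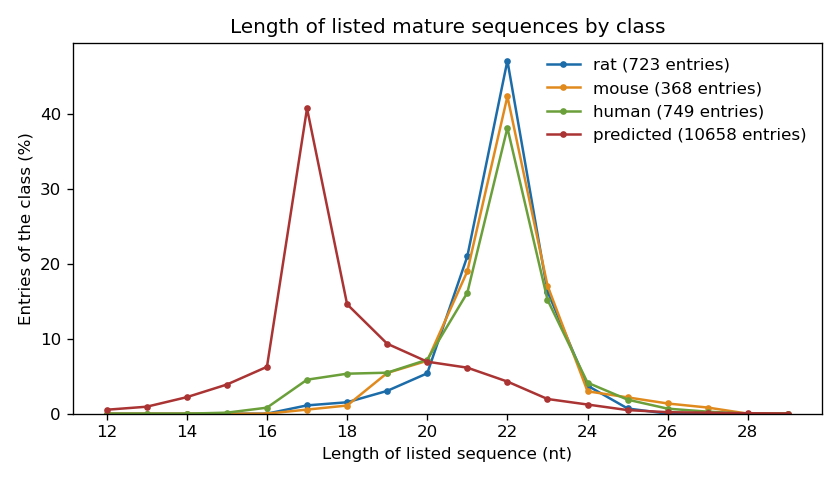
Length of the listed mature sequence in nt (x axis) against the percent of entries of each class with that length (y axis), with 1 line each for the 723 rat, 368 mouse, 749 human and 10658 predicted entries. At 22 nt lie 47.2% of rat, 42.4% of mouse and 38.2% of human entries, while 40.8% of predicted arms are 17 nt long and 4.29% are 22 nt long.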

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

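All alternatives reported here were chosen after seeing the data. The 19 planned ones were not run, because they concern read counts, which could not be tied to a sample and were left out. No paired analysis was possible because each group has 1 sample and neither count column could be assigned to one. The number of same-strand pairs of rat entries, 27 at a minimum of 16 shared bases, was 44 at 14 bases, 13 at 18 and 4 at 20. Complementary pairs, 59 at 16 bases, numbered 69 at 14, 48 at 18 and 36 at 20. Predicted arms sharing a stretch with a rat entry, 46 at 16 bases, numbered 83 at 14, 8 at 18 and 3 at 20. Rat entries in a pair of either kind, 137 at 16 bases, numbered 158 at 14, 110 at 18 and 77 at 20. A longer minimum can only lower each count. Complementary pairs outnumbered same-strand pairs at each minimum length tried, but these nested counts are not separate checks. Same-strand counts are held down by the rule, since a mismatch breaks the shared stretch. They are also held down because an entry with several precursors is listed once.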
